A study of Homo sapiens with 3 samples.

How the data were processed

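RNA from 3 pools of SUM52 cells was sequenced as 1 directional poly(A) library each, per the labels' protocols. Those protocols say that RNAs were pooled in equal amounts, without the number of cultures, and mention both poly(A)-positive and poly(A)-negative fractions; the libraries are described here as poly(A)-selected. Each library's group was taken from its title, since the description of the K907A sample also mentions a control virus. The deposited values are FPKM, fragments scaled by transcript length and by the library's mapped fragments. The submitters' processing notes name TopHat 1.4.1, Cufflinks 2.2.1, Cuffdiff and the hg19 build, without their order or settings. Per the file headers, each of 25156 assembled loci has 1 FPKM value per library, with a gene symbol, the nearest RefSeq accessions and a position. Starts are counted from 0 in the files and are given here from 1.

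FPKM are not counts, and read totals are not given in the sources used here, so no count model was used. Low values give a rough idea of depth. Of 357 olfactory receptor loci of about 0.94 kb, 23, 20 and 14 were above 0 in GFP, K599A and K907A, with medians of 0.15, 0.14 and 0.155 FPKM. If such a value stands for 1 fragment, 1 FPKM over 1 kb is about 7.17, 7.69 and 6.80 fragments. The smallest values of microRNA loci at 7 shared lengths were 0.859 times the GFP value in K599A and 0.967 times in K907A. A gene at 1 FPKM may therefore rest on few fragments, and very short transcripts reach high FPKM from 1 fragment.

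Of the loci, 1246 carry no name and were only counted. Rows of 1 symbol were summed and exact duplicates used once, which left 22500 symbols, 453 of them with several rows. Loci that merge several genes (314 symbols) were kept as 1 unit and never used as list members, which cost 17 list genes. Small RNAs named by pattern (1443 symbols) were left out, because FPKM of transcripts shorter than a fragment are unreliable. Genes with a mean of at least 1 FPKM over the 3 libraries were kept, 11169 in all. Log2 ratios used a pseudocount of 1, and genes were counted at an absolute log2 ratio of at least 1. No scaling was added to the deposited values.

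Lists of 33 gene groups were fixed from textbook knowledge before the data were examined. For lists with at least 5 members kept (29 lists), the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the central 95% was called apart; this describes these libraries and is no test of the conditions. The 3 contrasts gave 11, 10 and 10 such calls among 29 lists each. About 5% of lists of independently drawn genes would lie outside by construction. Listed genes can vary together and some lists share members, so no excess is read from these counts. Chance overlap under the shared GFP library came from 100 random reassignments of each gene's values to the libraries.

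Named genes followed a rule fixed before the data were examined. It took ERN1, XBP1, DNAJB9, HSPA5, DDIT3, BLOC1S1, RAB3B, FGFR2 and ESR1. Among genes with a mean of at least 5 FPKM it added the 12 highest and 12 lowest of each contrast and of both mutants together. Up to 4 members of each list followed, by size of ratio, and a part of these is named. After the data were seen, 16 rows above 10000 FPKM in 1 library and 0 in another were found, along with 8 let-7 precursors that the name pattern missed. Also found were 91 kept genes whose locus lists an accession of a microRNA, snoRNA or other small RNA in the RefSeq gene table of GRCh38.p14, of which only accessions and gene types were used. A further 236 kept genes list a noncoding RNA accession that this table does not hold; their RNA type is not known here, and they were not left out. The ranking was repeated without these rows and loci, and genes named from it are marked.

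The steps were tested on simulated libraries of 11068 genes for the contrast of K907A with GFP, with a noise of 0.152 (SD, log2). The noise was set from the quartiles of the log2 ratios of K599A against GFP (-0.160 and 0.130). Those of K907A against GFP lay further apart (-0.135 and 0.224), so the rates need not hold for that contrast. Of 50 genes each, 100% were recovered at a simulated log2 change of 2, 90% at 1.5, 72% at -1.5 and 96% at -2, and 0% of 10868 unchanged genes were called. Every gene was given the same noise, whatever its expression, and no extreme rows were simulated. The 0% therefore does not carry over to low genes or to such rows. Of 200 unchanged lists of genes drawn independently at random, 4.5% fell outside the central range.

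Alternatives covered pseudocounts of 0.1 and 5, median-ratio and TPM-like scaling, filters on low values, small RNAs kept, the highest row of a symbol, a log2 threshold of 0.5, unmatched random lists, and members shared between lists left out. Scaling alternatives divided each library by 1 factor before the pseudocount of 1 was added, which flattens low genes where the factor is large. Restricting to loci with an accepted quantification status was not run, as the files carry no such column. For the microRNA question, 3′ UTRs came from the GENCODE v29 annotation of GRCh38 for 9306 of 11169 genes (83.3%), each with at least 50 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.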

Results

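Poly(A)-selected RNA of SUM52 cells, an established human breast cancer line of luminal type, was sequenced in 3 libraries, 1 per group. The cells had received an adenovirus carrying GFP as control, or an adenovirus carrying the kinase mutant K599A or the RNase mutant K907A of IRE1, both named dominant-negative in the labels. IRE1, encoded by ERN1, is an ER membrane sensor of the unfolded protein response (UPR). Its RNase splices XBP1 mRNA into the form that encodes the active transcription factor XBP1s, and it can cut other RNAs (RIDD). The series asks what loss of IRE1 function does to these cells, with microRNAs proposed as targets of its RNase as the focus. With 1 library per group there was no replicate error and no test: higher and lower describe these libraries only. Values are FPKM, and log2 ratios are of FPKM + 1, which understates changes of low genes. The files listed 25156 loci, with values above 0 at 17369 in GFP, 17287 in K599A and 16804 in K907A. After filtering, 11169 named genes were compared.

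ERN1 checked the labels. Its locus (NM_001433, chromosome 17, hg19 positions 62118484 to 62207547) had 18.7 FPKM in GFP, 15384 in K599A and 7352 in K907A, 824-fold and 394-fold the GFP value. The files give 1 value for the locus, so native and delivered transcripts are summed, and the base changes themselves were not read here. Total XBP1 (chromosome 22, 29190548 to 29196560) was 370 FPKM in GFP, 362 in K599A and 272 in K907A, and spliced and unspliced forms are not separated in these values.

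The comparison of K907A with GFP asked what the RNase mutant did to gene expression. The library given K907A had higher levels of most genes of the secretory pathway. Of 44 XBP1s target genes, 43 were higher than in GFP and 30 of them at least 2-fold, with a median log2 ratio of 1.12 that lay above all 10000 random lists matched on expression (percentile 100). DNAJB9, an ER co-chaperone and a standard XBP1s target (chromosome 7, 108210189 to 108215294), was 20.4 FPKM against 5.00 in GFP. CRELD2, an ER stress-induced protein, was 175 against 31.3, and HYOU1, an ER chaperone, 410 against 94.4. All 17 measured ATF6 target chaperones were higher, 14 of them at least 2-fold, with a median of 1.58 (percentile 100). Among them HSPA5 (BiP, the main ER HSP70; chromosome 9, 127997127 to 128003666) was 1111 against 247, SDF2L1 190 against 36.8, and MANF 341 against 74.6. The lists share members, and 41 XBP1s targets outside the ATF6 list had a median of 1.07 (percentile 100).

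Other ER groups were higher in the K907A library as well. Their lists share members with the XBP1s and ATF6 lists, among them EDEM2 and STT3A (XBP1s) and DERL3 (ATF6). They are therefore not independent of those lists, though the calls of these ER lists did not change with members shared between lists left out. Of 28 genes of ER-associated degradation, 23 were higher than in GFP and 9 at least 2-fold (median 0.63, percentile 100), led by DERL3 (6.81 against 1.62) and EDEM2, a mannose-trimming factor (44.7 against 14.4). Of 32 N-glycosylation genes, 28 were higher and 6 at least 2-fold (median 0.54, percentile 100), among them OSTC (199 against 67.3) and the catalytic subunit STT3A (114 against 41.7). Of 37 genes of ER-Golgi transport, 35 were higher and 9 at least 2-fold (median 0.55, percentile 100), including TMED9 (315 against 116) and PREB (152 against 48.5). RAB GTPases (median 0.18, percentile 99.7) and cholesterol biosynthesis genes (median 0.23, percentile 99.6) stood above random lists by less, and not under the planned TPM-like scaling (73.5 and 73.8), with RAB1A, which acts in ER to Golgi traffic, at 94.8 against 51.5 and MVD at 14.4 against 6.86.

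Among the genes with the highest ratios in this contrast, BHLHA15 (MIST1, a transcription factor of secretory cells; chromosome 7, 97841566 to 97845891) was 139 FPKM in K907A against 5.94 in GFP, a 23.5-fold difference. MZB1, an ER protein that aids antibody secretion (chromosome 5, 138723204 to 138725689), was 216 against 16.9, or 12.8-fold. AGR2, an ER disulfide isomerase of mucus-secreting and luminal cells (chromosome 7, 16832264 to 16844738), was 7494 against 1160, or 6.46-fold. FICD, which modifies BiP, was 23.8 against 4.04. Lower list members included DGAT2, a triglyceride synthesis enzyme (7.47 against 16.8), and the histone gene HIST1H4H (5.14 against 14.4). These 2 genes were among the 12 lowest only in the ranking repeated after seeing the data. TSPYL2 (32.8 against 6.37) and CDSN, a cornified-layer adhesion protein (2.91 against 11.5), were named after seeing the data, once loci that list a small RNA accession were left out. IL32 was 0.78 against 4.77 and CTGF 1.41 against 3.98.

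Lists of the PERK branch and of RIDD differed less in the K907A library. The PERK-ATF4-CHOP list of 36 genes had a median of 0.23, inside the central 95% of random lists (percentile 95.2) but above it among unmatched lists (percentile 99.95), and only WARS was at least 2-fold higher (163 against 76.6). DDIT3 (CHOP) was 179 FPKM against 151. Of 20 reported RIDD substrates, 10 were higher and 10 lower (median -0.03, percentile 3.47, inside the central range). PDIA4, which ATF6 also induces, was 115 against 29.5, and DGAT2 was lower as above. BLOC1S1, a well-known RIDD substrate, shares a locus with RDH5 in the files, and that locus had 69.7 FPKM in GFP, 75.3 in K599A and 76.9 in K907A.

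In all, 163 of 11169 genes were at least 2-fold higher and 64 at least 2-fold lower in K907A than in GFP. Without isolated extreme rows, let-7 precursors and loci that list a small RNA accession, they were 154 and 47 of 11068. Scaling each library to one sum without ERN1 and those extreme rows, added after seeing the data, gave 121 higher and 133 lower. The planned scaling, which kept the extreme ADRA2C row in its sum, gave 5 and 11079. That row held 96.4% of the K907A FPKM sum over all loci. The median log2 ratio of all genes was 0.04, and 89.2% of genes lay within 0.5 of 0.

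The comparison of K599A with GFP asked the same of the kinase mutant. Lists of secretory pathway genes did not stand above random lists here. Of 44 XBP1s target genes, 30 were lower than in GFP and 14 higher, none by 2-fold, and the median of -0.09 lay below the random lists (percentile 0.00). DNAJB9 was 3.08 FPKM against 5.00 in GFP, EDEM2 9.68 against 14.4 and SEC24D, a COPII coat subunit, 6.21 against 9.20. Against random lists not matched on expression, the same median was inside the central range (percentile 3.16). ER-Golgi transport genes were also lower in 29 of 37 cases (median -0.09, percentile 0.02, or 5.20 among unmatched lists). ATF6 target chaperones had a median of 0.14 (percentile 91.2), and HSPA5 alone was at least 2-fold higher, at 577 against 247. ER-associated degradation (median 0.01, percentile 42.2), N-glycosylation (-0.05, 5.65), RAB GTPases (-0.03, 28.9) and cholesterol biosynthesis (-0.07, 8.95) were inside the central range. So were the PERK-ATF4-CHOP list (median 0.12, percentile 96.3), with DDIT3 at 158 FPKM, and reported RIDD substrates (median 0.07, percentile 84.6). The PERK-ATF4-CHOP list stood apart in K599A without a filter on low values (percentile 97.6), without members shared between lists (98.0) and among unmatched lists (99.9), and ATF6 chaperones did so among unmatched lists (99.0).

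Cytosolic heat shock genes were higher in the K599A library. All 20 were higher than in GFP and 6 at least 2-fold, with a median of 0.71 (percentile 100). HSPA1A, the inducible cytosolic HSP70, was 231 FPKM against 32.3, a 7.14-fold difference, and its near-identical copy HSPA1B 131 against 21.7. Reads of these copies can be exchanged, so their separate values are uncertain. HSP90AA1 was 459 against 160, and the small heat shock protein HSPB1 283 against 99.3. CRYAB, a small heat shock protein outside the list, was 12.4 against 2.16 in GFP, and was higher in K907A too, at 7.35. In K907A, 17 of the 20 were higher than in GFP and 2 at least 2-fold, with a median of 0.12 inside the central range (percentile 41.4). HSPA1A was 62.4 and HSPA1B 44.9 FPKM there, while HSP90AA1 was 152 and HSPB1 110. HSPA6, a low gene, was 0.14 FPKM in GFP, 1.04 in K599A and 1.97 in K907A.

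Smaller list medians stood apart from random lists in K599A. NF-kB and inflammatory cytokine genes (median 0.15, percentile 98.7; IRF1 at 10.2 against 5.42), NRF2 response genes (median 0.15, percentile 98.2; AKR1C3 at 15.3 against 8.12) and immediate early genes (median 0.11, percentile 98.4) were above them, and glycolysis and hypoxia genes below (median -0.08, percentile 1.23; NDRG1 at 15.5 against 27.4). IFI6, an interferon-induced gene, was 9.47 against 25.8, while the type I interferon list was not apart (median -0.04, percentile 53.9). The NF-kB call was lost at a pseudocount of 5 (percentile 96.0) and without shared members (96.7), and the NRF2 call at a mean of at least 5 FPKM (94.3). That filter also ended the immediate early call, as did no filter (65.8), and the glycolysis call was lost with small RNAs kept (2.79) and among unmatched lists (11.4). In K907A these 5 lists were all inside the central range, with medians of 0.11, 0.15, 0.05, 0.05 and 0.08 in that order.

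In all, 47 genes were at least 2-fold higher and 44 at least 2-fold lower in K599A than in GFP, or 37 and 26 of 11068 without the rows and loci named above. The median log2 ratio of all genes was -0.02, and 94.4% of genes lay within 0.5 of 0.

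**Figure D1:**
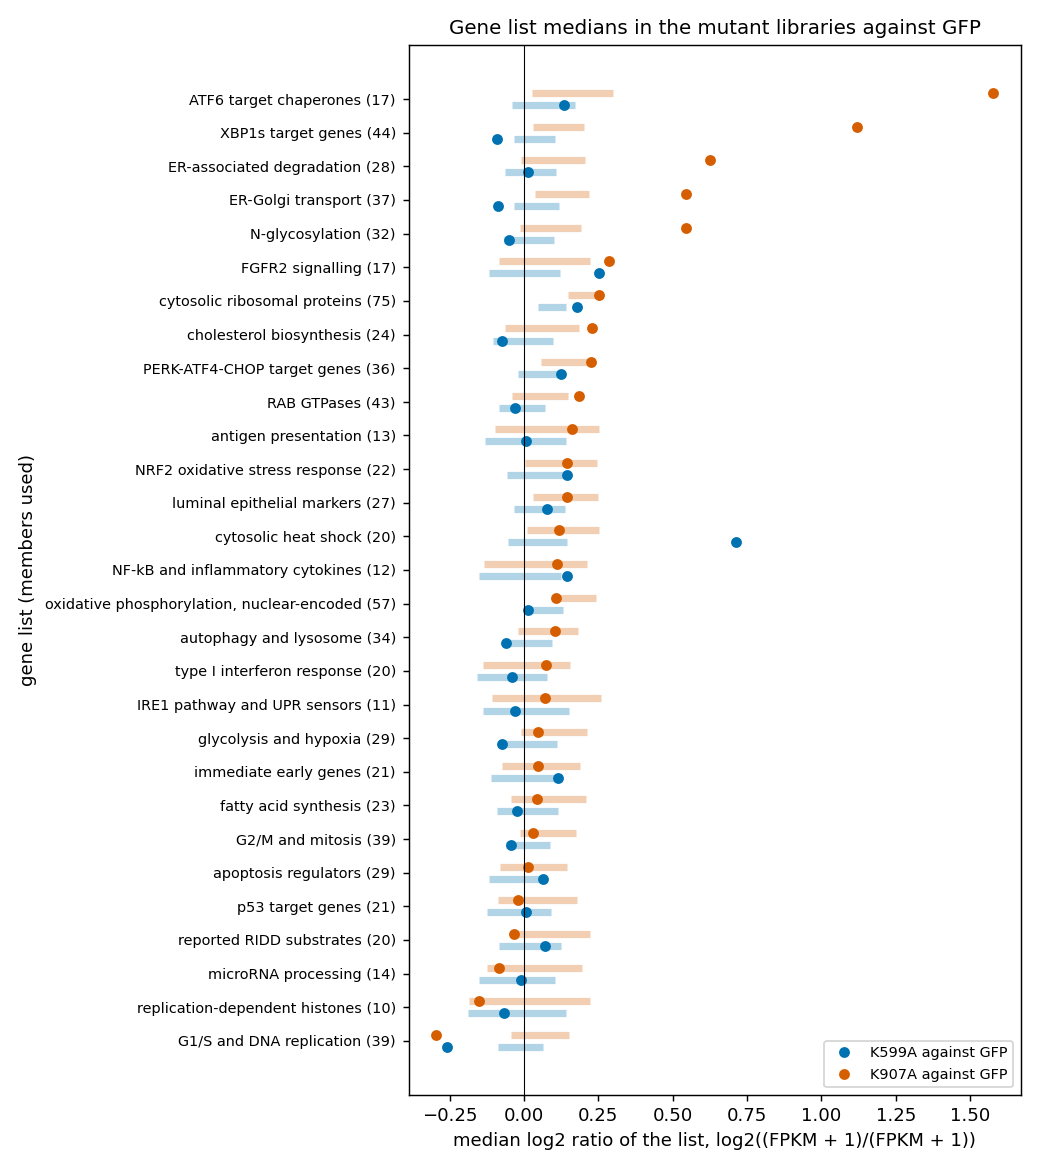
Median log2 ratio against GFP (x axis, log2 of FPKM + 1) of each gene list (y axis, members used in brackets) in the K599A library (blue points) and the K907A library (orange points); pale bars span the central 95% of 10000 random lists matched on expression. XBP1s targets lie at 1.12 in K907A and -0.09 in K599A, and cytosolic heat shock genes at 0.12 and 0.71.

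The mutant libraries were then set against each other. K907A had 144 genes at least 2-fold higher and 43 at least 2-fold lower than K599A. The TPM-like scaling without ERN1 and extreme rows gave 124 and 69, and the planned one 3 and 11055. XBP1s targets were higher in 42 of 44 cases (median 1.25, percentile 100), ATF6 target chaperones in all 17 (median 1.35, percentile 100) and ER-Golgi transport genes in 36 of 37 (median 0.62, percentile 100). ER-associated degradation (24 of 28 higher, median 0.62, percentile 100) and N-glycosylation genes (27 of 32, median 0.62, percentile 100) were higher too, and RAB GTPases (median 0.19, percentile 99.9) and cholesterol biosynthesis genes (median 0.22, percentile 99.92) by less. The cholesterol call was lost at a mean of at least 5 FPKM (percentile 92.6), and it and the RAB call were lost under the planned TPM-like scaling (80.7 and 88.6). AGR2 was 7494 FPKM in K907A against 649 in K599A, GAS6 179 against 24.8, and FICD 23.8 against 3.02. Cytosolic heat shock genes were lower in 19 of 20 cases (median -0.63, percentile 0.00). Apoptosis regulators (median -0.07, percentile 1.29) and replication-dependent histones (median -0.18, percentile 0.85) were also below random lists. The histone call was lost at a mean of at least 5 FPKM (percentile 22.7) and the apoptosis call without shared members (3.21), and both under that scaling (26.0 and 12.8). ERN1 itself differed, at 7352 FPKM against 15384.

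Genes that differed from GFP the same way in both mutant libraries were counted last. At least 2-fold higher in both were 20 genes, and at least 2-fold lower 26. The 20 include the delivered gene ERN1 itself and the let-7 precursors MIRLET7C and MIRLET7F2. Because both contrasts share the GFP library, reassigning each gene's values at random gave means of 14.3 and 50.1. Independent lists would share 0.686 and 0.252. Reassignment also moves differences of 1 mutant library into GFP, so its means are not the overlap from the shared control alone. Without the rows and loci named above the counts were 16 and 12, beside 9.20 and 40.9 after reassignment. ERN1 was still among the 16. How much of the overlap comes from the shared control cannot be read from these values. Across genes, which are not independent replicates, the 2 sets of log2 ratios correlated at r = 0.56 (reassigned values 0.50), with a covariance of 0.134 (reassigned 0.116). Without the rows and loci named above, both lay nearer to the reassigned values. There r was 0.53 (reassigned 0.50) and the covariance 0.053 (reassigned 0.052).

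Named genes higher in both included CALB2 (calretinin; 9.20 FPKM in GFP, 39.7 in K599A and 32.2 in K907A) and VGLL1, a TEAD cofactor (2.85, 8.42 and 7.76). The hair keratins KRT81 (1426, 3425 and 3188) and KRT86 (998, 2207 and 2522) are near-copies whose reads can be exchanged. ATF5, a UPR-linked transcription factor, was 14.6, 127 and 115, but its locus lists a microRNA accession. FGFR2 signalling genes were above random lists in both (medians 0.25 and 0.29, percentiles 99.99 and 99.7), with DUSP6, a feedback phosphatase of ERK, at 163, 313 and 241 and ETV5 at 9.52, 16.5 and 16.8. Between the mutants, whose contrasts share the GFP library, the list was not apart (median -0.06, percentile 4.67), except without a filter (1.69) and under the planned TPM-like scaling. In K907A the call against GFP was lost without a filter on low values (median 0.12) and at a mean FPKM of at least 5 (median 0.21). FGFR2 itself, which is amplified in SUM52, was 1285, 1473 and 1300 FPKM.

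G1/S and DNA replication genes were lower in both mutant libraries than in the GFP library they share, so a deviation of that library alone would give the same picture. Of 39, 37 were lower in K599A and 36 in K907A (medians -0.26 and -0.29, percentile 0.00 in each), with RRM2, a ribonucleotide reductase subunit, at 110 FPKM in GFP, 70.2 in K599A and 71.1 in K907A, and CCNE2 (cyclin E2) at 6.10, 2.65 and 3.89. CDC6 was an exception in K907A, at 24.6 against 11.1. Between the mutants the list was not apart (median 0.04, percentile 36.2). G2/M and mitosis genes were not apart (medians -0.04 and 0.03, percentiles 7.54 and 14.7). RAB3B, a RAB GTPase of regulated secretion (chromosome 1, 52373628 to 52456436), was 11.7, 6.29 and 6.65 FPKM, log2 ratios of -0.80 and -0.73. Oxidative phosphorylation genes were below expression-matched lists in both (medians 0.01 and 0.11, percentiles 1.72 and 1.79), although most members were higher than in GFP. Both calls were lost without a filter (percentiles 3.02 and 2.83), with small RNAs kept and among unmatched lists (83.2 and 93.4). Cytosolic ribosomal protein genes were above random lists in K599A (median 0.18, percentile 99.99) and inside the range in K907A (median 0.25, percentile 96.7), where it was above them without a filter (98.3), with small RNAs kept (98.6) and among unmatched lists (100).

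The lowest ratios in both mutants belonged to loci whose FPKM can rest on a few fragments. CPEB2, ZNF750, ZKSCAN2 and PSMB10 each owed their GFP values of 42854 FPKM and above to 1 row listed at 0 in both mutants. FSTL1 (166 FPKM in GFP, 0.05 in both mutants), WHSC2 (269, 15.2 and 14.1), AMH (110, 6.54 and 6.68) and DGCR8, a microRNA processing factor (114, 12.8 and 7.15), list a small RNA accession in their locus. TRAPPC4 (169, 24.0 and 35.1) was also among the lowest; its locus lists a noncoding RNA accession of unknown type. Once such rows and loci of known small RNAs were left out, the lowest also included the tRNA synthetase IARS (360, 165 and 200) and MUCL1, a mammary mucin-like protein (140, 76.1 and 81.3), both named after seeing the data.

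**Figure D2:**
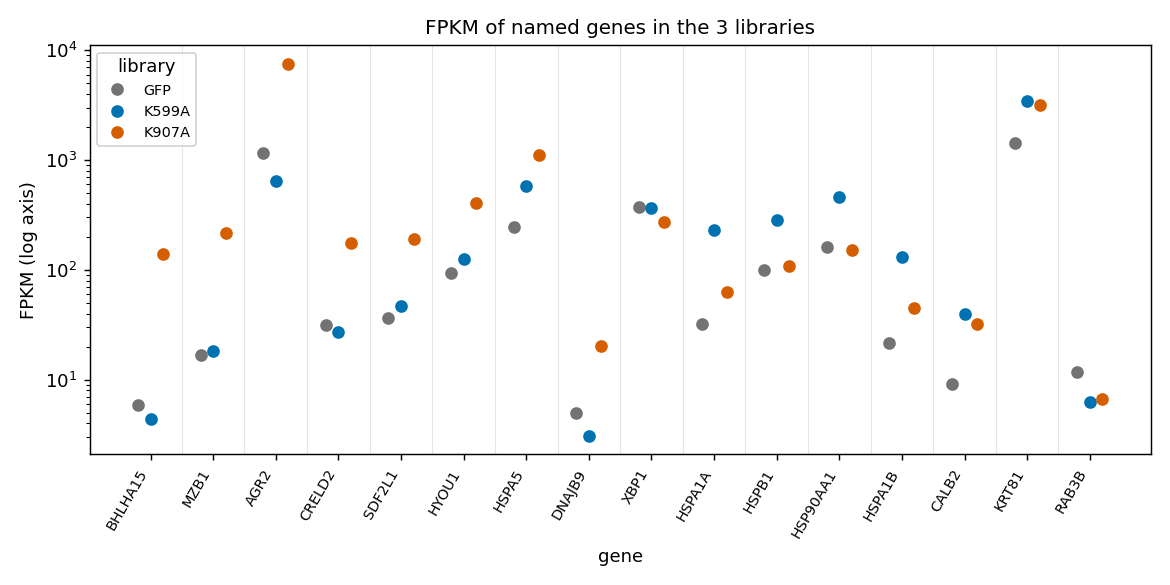
FPKM (y axis, log scale) of 16 named genes (x axis) in the GFP (grey), K599A (blue) and K907A (orange) libraries, 1 point per library. BHLHA15 stands at 139 FPKM in K907A against 5.94 in GFP, HSPA1A at 231 in K599A against 32.3, and RAB3B at 6.29 and 6.65 against 11.7.

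Further lists were inside the central range against GFP in both mutants. They were IRE1 pathway and UPR sensors (medians -0.03 and 0.07), luminal epithelial markers (0.08 and 0.14), p53 targets (0.01 and -0.02), fatty acid synthesis (-0.02 and 0.04), antigen presentation (0.01 and 0.16), apoptosis regulators (0.07 and 0.01), replication-dependent histones (-0.07 and -0.15), autophagy and lysosome (-0.06 and 0.10) and microRNA processing (-0.01 and -0.08). Apoptosis regulators stood above random lists in K599A at pseudocounts of 0.1 (percentile 98.2) and 5 (97.9), without a filter (98.3) and under both TPM-like scalings (97.6 and 97.8). Histones stood below them in K907A at a pseudocount of 5 (percentile 1.57) and in K599A at a mean of at least 5 FPKM (2.37). Markers of other cell types were sparse. Of 30 basal and mesenchymal markers only S100A4, TAGLN, MMP9 and ITGA6 reached a mean of 1 FPKM, of 15 leukocyte markers only CD68 (0.83, 0.97 and 1.43), and of 18 fibroblast and endothelial markers only CLDN5 (15.5, 16.7 and 7.37) and COL1A1. ESR1, the estrogen receptor, was 0.32, 0.41 and 0.37 FPKM. No mitochondrially encoded gene was named, and the single unnamed mitochondrial locus had 4126, 3740 and 4353 FPKM.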

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

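All tests of explanations in this part were chosen after the results were seen. Gene lists that stood apart from random lists in opposite directions in the mutant libraries were XBP1s targets, with a median log2 ratio of 1.25 between K907A and K599A, and ER-Golgi transport genes, with 0.62. The difference was not tested, since each group is 1 library, and both K599A calls were lost among unmatched lists (percentiles 3.16 and 5.20). Loci without a name enter no comparison above. Of 1243, 31 were at least 2-fold higher in both mutant libraries than in GFP and 104 at least 2-fold lower. Reassigning each locus's values among the libraries, which share the GFP control, gave means of 46.6 and 69.9, which are no pure chance level either.

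XBP1s targets were higher in the library labelled K907A, a construct the labels name dominant-negative, and slightly lower in K599A. Library scaling is argued against, because the median log2 ratio of all genes was 0.040 while the list stood at 1.12. The amount of delivered ERN1 transcript cannot be told apart from the mutation: K599A, with more of it, had a list median of -0.091, but no pair of libraries differs in the amount alone. ER stress through all sensor branches stays open. The ATF6 list had a median of 1.58 (percentile 100), and the PERK-ATF4-CHOP list stood at percentile 95.2 of random lists, or 99.95 among unmatched lists. IRE1 RNase activity in these cells, or a library holding another construct, cannot be told apart here, because the total XBP1 ratio of -0.44 does not separate spliced from unspliced mRNA and no base of ERN1 can be read.

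Cytosolic heat shock genes were higher in K599A. Reads shared between HSPA1A, HSPA1B and other HSPA genes do not account for it, since the list without them had a median of 0.67. Library scaling is argued against by an all-gene median of -0.020. The amount of ERN1, 2.09 times that in K907A, cannot be told apart from the mutation, because no pair of libraries differs in it alone.

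Genes at least 2-fold lower in both mutants often sat in loci with a small RNA, and 2 more listed a noncoding RNA accession whose type is not known here. Of these 26 genes, 38.5% listed a small RNA accession (exact 95% interval 20.2% to 59.4%), against 0.815% of all genes kept, so short transcripts with few fragments may set many of these ratios. Of 24 loci with a small RNA that differed by 2-fold in any contrast, 12 were highest in GFP, 6 in K599A and 6 in K907A. The share was also above that of all genes kept among the genes higher in both, at 10% (1.23% to 31.7%). It was 19.8% of those 2-fold different in K599A (12.2% to 29.4%) and 7.49% in K907A (4.42% to 11.7%). The K599A and K907A sets contain the genes counted in both mutants, so they partly count the same loci again. An effect of the constructs on the small RNAs themselves was not tested.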

How the results depend on the processing

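Alternatives that leave out extreme rows or loci with a small RNA, and the second TPM-like scaling, were chosen after seeing the data; the others were fixed before. Restricting loci by quantification status was not run. XBP1s targets in K907A stood above all random lists under every alternative run (medians 0.93 to 1.15, and -3.07 under the planned TPM-like scaling), as did ATF6 chaperones (percentile 100 in each), and the call of RIDD substrates did not change in either mutant. The XBP1s median of -0.091 in K599A was no longer apart against unmatched lists. PERK-ATF4-CHOP genes became apart in K599A without a filter (0.12), without shared members (0.14) and against unmatched lists (0.12), and in K907A against unmatched lists (0.23), as did ATF6 chaperones in K599A (0.14). Between the mutants, FGFR2 signalling, NF-kB and antigen presentation genes became apart without a filter (percentiles 1.69, 2.28 and 2.19), and interferon genes at a pseudocount of 0.1 (97.8), a mean of at least 5 FPKM (97.7) and the second TPM-like scaling (97.6). The cause was not tested. Over all combinations of list, contrast and alternative, 28 lost and 28 gained a call, 1075 kept theirs, and none reversed. The same list and contrast enters once per alternative, so these are not counts of lists.

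Counts moved with the pseudocount, which sets how far low genes can differ. At 0.1, K599A had 89 genes higher and 84 lower than GFP, K907A 133 lower, K907A against K599A 89 lower, and both mutants 43 higher. At 5 these contrasts gave 26 and 25, then 88 and 21, then 93 and 21, and both mutants 9 and 17. A mean of at least 5 FPKM, which tests fewer genes, gave 29, 32 and 27 lower in the 3 contrasts. With small RNAs kept, K599A had 122 higher and 137 lower, K907A 180 lower, K907A against K599A 131 lower, and both mutants 47 and 92. At a log2 threshold of 0.5 the contrasts gave 352 and 273, 809 and 398, and 633 and 272, and both mutants 158 and 124. Without extreme rows, let-7 precursors and loci that list a small RNA, 26 genes were lower in K599A and 12 in both mutants, where leaving out only the rows and precursors gave 39 and 22.

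The planned TPM-like scaling was set by 1 row of ADRA2C, and moved the median of all genes in K907A by -3.33 against GFP and by -3.23 against K599A. It gave 5 genes higher and 11079 lower in K907A than in GFP, 3 and 11055 against K599A, 3 and 52 in both mutants, and r = 0.21. It also ended the K907A calls of RAB GTPases, cholesterol biosynthesis, FGFR2 signalling and oxidative phosphorylation genes against GFP, and those of RAB GTPases (percentile 88.6), cholesterol biosynthesis (80.7), apoptosis regulators (12.8) and histones (26.0) against K599A. Under it glycolysis genes stood below random lists against GFP (0.06) and K599A (1.79), as did ribosomal proteins (0.39), NF-kB (0.92), NRF2 (1.14), FGFR2 signalling (1.31) and IRE1 pathway genes (1.56) against K599A. Relative to that shift, IL32 turned to 0.71 and 0.96 against GFP and K599A, and CTGF to 0.97 against GFP. A common factor leaves the FPKM of genes in a library unchanged relative to each other. These turns therefore come from the pseudocount of 1, added after the division. The calls lost or gained under this scaling can come from the same step or from matching on the scaled expression. The TPM-like scaling without such rows gave 133 genes lower than GFP and 69 lower than K599A, with shifts of -0.19 and -0.11.

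Without the extreme rows, with or without loci that list a small RNA, 6 genes turned direction, because their ratios came from those rows. ADRA2C went to 0.25 in K599A, to -0.69 in K907A and to -0.94 between the mutants, and ZNF750 to 0.025 and 0.11 against GFP. PSMB10 went to 0.54 and TCERG1L to -0.084 in K599A, ZKSCAN2 to 0.16 in K907A, and RPS6KA2 to 0.19 between the mutants. No depth is given beside the FPKM, so which low genes can be told apart is not known.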

Other observations

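The link of MIR96, MIR374A and MIR3607 to the series' question was taken from memory, and the microRNA loci hold little signal. MIR96 and MIR374A were listed at 0 in all 3 libraries. MIR3607 was listed at 0 in GFP and K599A and at 62.4 FPKM in K907A. MIR182 was 221, 116 and 91.8 FPKM in GFP, K599A and K907A, and MIR183 78.5, 72.7 and 0. Poly(A) libraries hold few precursors, and the number of fragments behind each of these values is not known.

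A hypothesis set before the result was seen was that mutant cells hold more of miR-96-5p, miR-374a-5p, miR-3607-5p or miR-3607-3p, in which case genes with a 3′ UTR seed site would have lower log2 ratios than under control seeds of the same bases. The choice of these microRNAs and their sequences came from memory. For miR-96-5p (836 genes with a site) the difference stood at percentile 39 of control seeds in K599A and 23 in K907A. For miR-374a-5p (1521 genes, 34 control seeds) it was 97.1 and 52.9, for miR-3607-5p (973 genes) 74.5 and 56, and for miR-3607-3p (1541 genes) 86 and 18.5. None lay outside the central 95% in these 8 comparisons. The highest, 97.1 for miR-374a-5p in K599A, was on the side opposite to the hypothesis. Its 34 control seeds give only coarse percentiles and had sites in more genes (median 2192.5). The hypothesis stays open, since a shift smaller than the spread of control seeds would not show.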
